A study of Homo sapiens with 9 samples.

How the data were processed

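RNA from 9 HK-2 libraries was made, per the labels, from Trizol extracts with 2 ug of total RNA and a SMARTER mRNA-Seq kit. The deposited table holds 163046 RefSeq transcripts and no unit in its header. The deposited values were taken as FPKM from the values themselves: they are not whole numbers, their sums differ between libraries (CV 4.33%), and the sums of value times transcript length are nearly constant (CV 1.43%, over 57436 transcripts with a paired length), as FPKM would give and TPM or coverage would not. The aligner, quantifier, annotation release and filters used by the authors are not given in the sources used here. The labels name the hg19 build. No whole reads could be recovered from the low values, so depth is unknown and no counting intervals were computed.

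Transcripts were paired with genes by accession in a RefSeq gene table on GRCh38.p14, used only for names and neighbours. The table paired 111697 transcripts (68.5%) with 31061 genes, and FPKM was summed per gene. The other 51349 transcripts, of which 50402 were predicted models and 947 curated, held 8.51 to 9.99% of FPKM per library, so some gene totals are incomplete. No coordinates are printed because the builds differ. Mitochondrially encoded mRNAs, a list of 13, had 0 members in the table. Marker lists written beforehand for other cell types had few members at 1 FPKM in 3 libraries: fibroblast 2 of 9, endothelial 1 of 10, leukocyte 2 of 11, podocyte 1 of 8 and distal tubule 2 of 13.

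Genes with at least 1 FPKM in at least 3 libraries (11686) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes). All 9 libraries entered 1 model of group means, with no block. The 3 comparisons were TGF-β against control, labelled knockdown with TGF-β against TGF-β, and labelled knockdown with TGF-β against control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Folds and log2 changes come from this fit and include the pseudocount of 1, so they are smaller than ratios of mean FPKM for genes of low level. This model was the one set for a table without counts. Model, groups, comparisons, gene lists and the rule for naming genes were chosen before the data were examined.

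Fixed gene lists with at least 5 tested members were compared with all other tested genes by camera (preset inter-gene correlation 0.01), adjusted over lists within a comparison. Estimated correlations and fry, a rotation test that asks whether a list's own genes move one way, were run beside it. Named genes are P4HA2-AS1, P4HA2, TRIM32 and ULK1, then the 6 highest and 6 lowest called genes of the first pair of comparisons (3 and 3 for the last) with a mean of at least 5 FPKM, an ordinary symbol and no overlap between the groups. The rule adds the 2 most changed called members of each list in the first pair of comparisons, and the 5 genes moved back with the largest smaller change. Not every gene that the rule names is printed. A gene counted as moved back when it was called in opposite directions in these comparisons, wherever it lay against control. P4HA2-AS1 was below the filter and was compared with a two-sided exact permutation test.

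The steps were tested on simulated data in which 200 genes were changed. The values were drawn independently for each gene and library, with 1 spread per gene in all 9 libraries. The shares below therefore do not cover correlated genes or libraries of unequal spread. For TGF-β against control (11477 genes), 66.2% of 1.5-fold, 92.3% of 2-fold and 97.0% of 4-fold changes were recovered, and 7.7% of calls were false. For labelled knockdown against TGF-β (11478 genes) the shares were 63.1%, 86.2% and 98.5%, with 5.8% false calls. For labelled knockdown against control (11475 genes) they were 63.1%, 86.4% and 98.5%, with 5.8% false calls. Alternatives covered the pseudocount, filters, scaling, array weights, curated transcripts, a transcript length correction, a replicate block, the groups in the fit, a fold threshold, list tests and leaving out each library. Count models, count normalizations and count filters were left out because the table holds no counts. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.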

Results

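RNA was sequenced from HK-2 cells, an immortalised line of human kidney proximal tubule epithelium. The 9 libraries formed 3 groups of 3: untreated control cells, cells given TGF-β for 24 h, and cells given TGF-β together with a short hairpin RNA against the long noncoding RNA P4HA2-AS1. TGF-β is a growth factor that drives kidney scarring. The dose reads 20 ng/ml in the sample labels and 10 ng/ml in the series design text. The labels describe no hairpin library without TGF-β and no library with a control hairpin, so the effect of the vector and the effect of losing P4HA2-AS1 were not separable. They also do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

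The values were FPKM, inferred as set out in the processing summary, and the number of reads per library is unknown. FPKM summed to between 341924 and 398019 per library, and 11042 to 11387 genes reached 1 FPKM. Pearson correlations across genes were 0.9695 to 0.9876 within groups and 0.9407 to 0.9601 between groups. TGF-β replicate 2 stood apart from the other 8 libraries. Its mean transcript length was 2349 nt, against 2538 to 2671 nt elsewhere, and ribosomal protein genes took 13.6% of its FPKM, against 10.5 to 12.1%. Its residual standard deviation was 0.26 on the log2 scale, against 0.16 to 0.21. The hairpin libraries had the longest mean transcript lengths, 2604 to 2671 nt, against at most 2583 nt in the other groups. Their ribosomal protein shares were the lowest, 10.46 to 11.25%, against at least 11.51%.

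P4HA2-AS1, the targeted transcript, was barely detected in any library. In control cells it measured 0, 0 and 0.0022 FPKM, with TGF-β 0.014, 0.029 and 0.022 FPKM, and in the libraries labelled as knockdown 0.019, 0.076 and 0 FPKM. A two-sided exact permutation test gave p = 0.1 for TGF-β against control and p = 0.9 for labelled knockdown against TGF-β, where 0.1 is the smallest p that 3 against 3 allows. These levels do not check the label, so those libraries are called labelled knockdown libraries throughout. P4HA2-AS1 overlaps P4HA2 in the reference annotation, and the strand of the counted reads was not given in the sources used here.

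TRIM32 and ULK1 are the genes that the study's title names beside P4HA2-AS1. TRIM32, a ubiquitin ligase, rose with TGF-β from 12.8 ± 0.57 to 21.4 ± 1.40 FPKM (SD, n = 3) and fell to 14.9 ± 1.07 FPKM in the labelled knockdown libraries. Its log2 changes were 0.69 ± 0.08 (SE) with a Benjamini-Hochberg adjusted p of 0.000312 in limma, and -0.50 ± 0.08 with an adjusted p of 0.00166. ULK1, the kinase that starts autophagy, rose 3.89-fold with TGF-β, a log2 change of 1.96 ± 0.16 (adjusted p = 4.69e-05 in limma). It measured 39.9 ± 8.60 FPKM with TGF-β and 38.0 ± 4.99 FPKM in the labelled knockdown libraries (SD, n = 3), a log2 change of -0.06 ± 0.16 that did not pass (adjusted p = 0.817). P4HA2, a collagen prolyl hydroxylase, had log2 changes of 0.62 ± 0.36 (adjusted p = 0.257) and -0.15 ± 0.36 (adjusted p = 0.777).

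**Figure D1:**
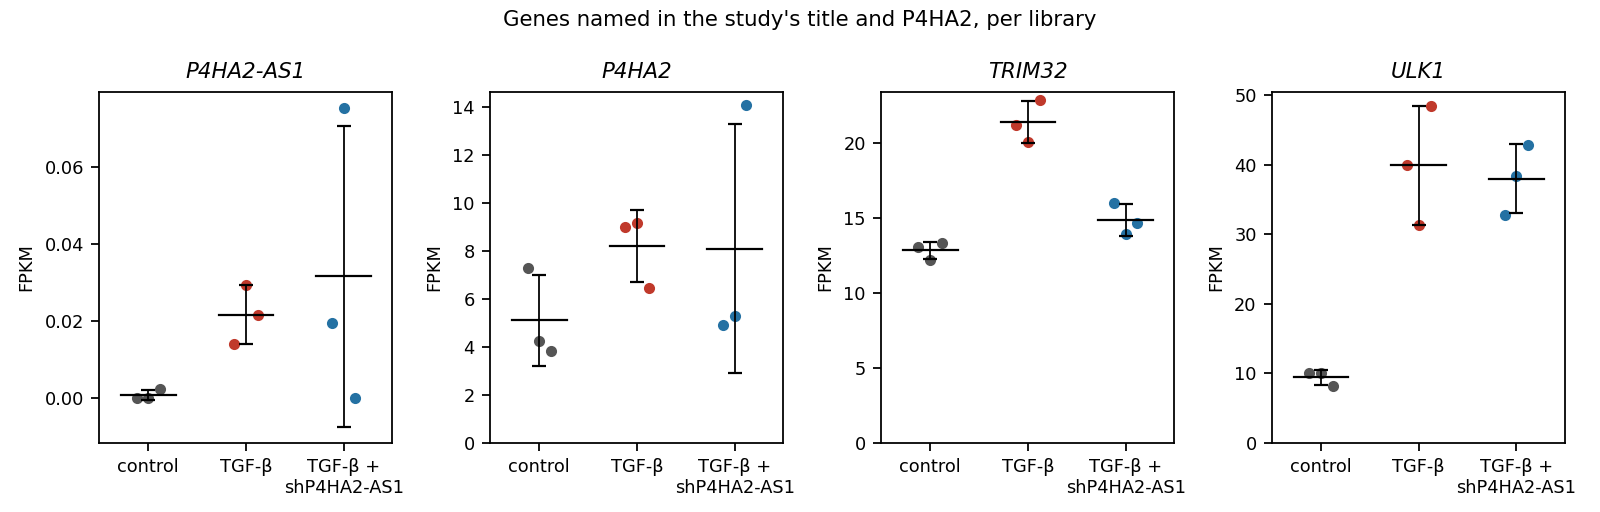
FPKM of P4HA2-AS1, P4HA2, TRIM32 and ULK1 in each of the 9 libraries, by group, with the mean and standard deviation of 3 libraries. P4HA2-AS1 stayed at or below 0.0756 FPKM in every library, while TRIM32 was higher with TGF-β than in both other groups.

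The first comparison asked what TGF-β changed in these cells. Of 11686 genes tested, 2864 changed, 1353 up and 1511 down, and 448 changed at least 2-fold (274 up, 174 down). The balance of rises and falls depended on the setting, from 1567 up and 1321 down under upper-quartile scaling to 1479 up and 2256 down without TGF-β replicate 2; array weights gave 2204 up and 3111 down. The strongest rises included COL1A1, the main chain of type I collagen, which went from 2.81 ± 0.20 to 37.0 ± 5.64 FPKM (SD, n = 3), a 9.92-fold rise. The transcription factor FOXS1 rose 12.5-fold, the RNA-binding protein gene CSDC2 rose 15.5-fold and ODAPH, a phosphoprotein gene known from enamel, rose 18.3-fold. CGB5 and CGB8, near-identical chorionic gonadotropin genes whose reads may be shared, rose 12.2-fold and 9.11-fold. The EGF receptor ligands AREG and EREG fell 15.3-fold and 13.8-fold, AREG from 50.6 ± 0.89 to 2.40 ± 0.58 FPKM. The AP-1 subunit FOSL1 fell 9.80-fold, the caveola gene CAVIN2 9.24-fold, the differentiation inhibitor ID2 8.26-fold and the neutrophil chemokine CXCL8 6.79-fold. Each of these 12 genes had a limma adjusted p of 3.05e-05 or lower and no overlap between the libraries of the 2 groups. COL1A2, which encodes the other chain of type I collagen, stayed at or below 0.016 FPKM in every library.

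Direct targets of TGF-β signalling rose as a group. Of 27 tested genes in the SMAD target list, 15 rose and 6 fell, counts that stayed at 15 and 6 when adjusted over the list alone; the list median was 0.63 (camera, Benjamini-Hochberg adjusted p = 0.00042; adjusted p = 0.0677 with an estimated correlation). PMEPA1, a feedback inhibitor of the pathway, rose 5.30-fold with a log2 change of 2.41 ± 0.05. The contractile and actin list rose, with 9 of 18 tested genes up and 1 down (10 and 2 adjusted over the list alone; camera adjusted p = 0.00223; adjusted p = 0.0677 with an estimated correlation). CNN1, a smooth muscle calponin, rose 3.18-fold and LIMA1 fell 2.13-fold. Mesenchymal genes had 6 up and 1 down of 15 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0284; adjusted p = 0.493 with an estimated correlation). That call was lost under median-of-ratios scaling (adjusted p = 0.0606), upper-quartile scaling (0.0576) and quantile normalization (0.0899), and without TGF-β replicate 1 (0.0949). The repressor SNAI1 rose 2.65-fold and the chromatin protein gene HMGA2 fell 2.07-fold.

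Autophagy genes rose, with 11 up and 1 down of 39 tested, the same counts when adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.413 with an estimated correlation). GABARAPL1, which coats autophagosomes, rose 4.20-fold from 29.3 ± 0.95 to 126.5 ± 7.77 FPKM (SD, n = 3). Inflammatory and NF-κB targets fell, with 1 up and 11 down of 21 (1 and 13 adjusted over the list alone) and a median of -1.20 (camera adjusted p = 1.57e-07; adjusted p = 0.0333 with an estimated correlation). The cytokine IL11 was the riser of that list, 7.12-fold up. Hypoxia and glycolysis genes fell, 1 up and 9 down of 28 (1 and 11 adjusted over the list alone; camera adjusted p = 0.0207; adjusted p = 0.0935 with an estimated correlation). The hexokinase gene HK2 fell 2.45-fold and the glucose transporter gene SLC2A3 1.83-fold.

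The remaining lists did not pass in this comparison. In the extracellular matrix list 6 genes rose and 2 fell of 20 (8 and 2 adjusted over the list alone; camera adjusted p = 0.133), and the list did pass without TGF-β replicate 2 (adjusted p = 0.00219), with array weights (0.0134; 0.0103 fitted gene by gene) and with the length trend removed (0.0382). Among its members THBS1, a matrix protein that activates TGF-β, fell 2.24-fold. Among collagen-modifying enzymes 4 rose and 1 fell of 18, the same adjusted over the list alone, and the cross-linking enzyme LOX rose 3.39-fold. Epithelial junction genes split, 6 up and 5 down of 18 by either adjustment, with CLDN4 rising 3.23-fold and CLDN1 falling 4.65-fold. Lysosomal genes had 5 up and 6 down of 31 by either adjustment, TFEB rising 3.58-fold and MITF falling 2.05-fold. Proximal tubule genes had 1 up and 3 down of 9 by either adjustment; the bicarbonate transporter SLC4A4 fell 1.82-fold. The stress response list had 9 up and 5 down of 25 by either adjustment, and the NRF2 list 3 up and 6 down of 21, with TXNRD1 falling 2.63-fold. Fatty acid oxidation had 3 up and 3 down of 24, cholesterol synthesis 3 and 2 of 24, and interferon-stimulated genes 3 and 1 of 23, the same adjusted over each list alone. Cell cycle genes had 0 up and 1 down of 37 (0 and 0 adjusted over the list alone). Tubular injury genes had 5 up and 4 down of 14 (5 and 6 adjusted over the list alone).

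Signs differed for 3 lists here. Tubular injury genes had a median of -0.32 and ran down in camera but up in fry, a rotation test of the list's own genes. Interferon-stimulated genes ran down in camera and up in fry, and fatty acid oxidation genes ran up in camera and down in fry.

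The second comparison asked what the hairpin changed in cells given TGF-β. In the labelled knockdown libraries 4252 of 11686 genes changed against TGF-β alone, 1830 up and 2422 down, and 423 changed at least 2-fold (141 up, 282 down). The balance was 2224 up and 2183 down under quantile normalization, 2123 up and 2295 down under median-of-ratios scaling, 1744 up and 2745 down under upper-quartile scaling, and 2392 up and 2409 down without TGF-β replicate 2. ANGPTL4, a lipoprotein lipase inhibitor, rose 8.37-fold from 5.04 ± 0.95 to 49.2 ± 1.28 FPKM (SD, n = 3). The glutathione-degrading enzyme gene CHAC1 rose 6.42-fold, FOSL1 5.97-fold, the ETS factor ETV5 5.49-fold and the activin subunit gene INHBE 5.45-fold. The heat shock chaperone HSPA1B, whose reads may be shared with its copy HSPA1A, rose 5.27-fold from 79.6 ± 3.09 to 423.3 ± 5.69 FPKM. FILIP1L fell 5.90-fold, the surface protein gene CD24 5.50-fold, the mitochondrial enzyme gene HOGA1 5.49-fold, SAMD11 5.06-fold and the GTPase exchange factor VAV3 4.35-fold. Each of these 11 genes had a limma adjusted p of 5.16e-06 or lower. The peptidase gene APEH fell 4.29-fold (log2 change -2.10 ± 0.44, limma adjusted p = 0.00634), with a wide spread in control cells of 8.41 ± 6.44 FPKM.

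**Figure D2:**
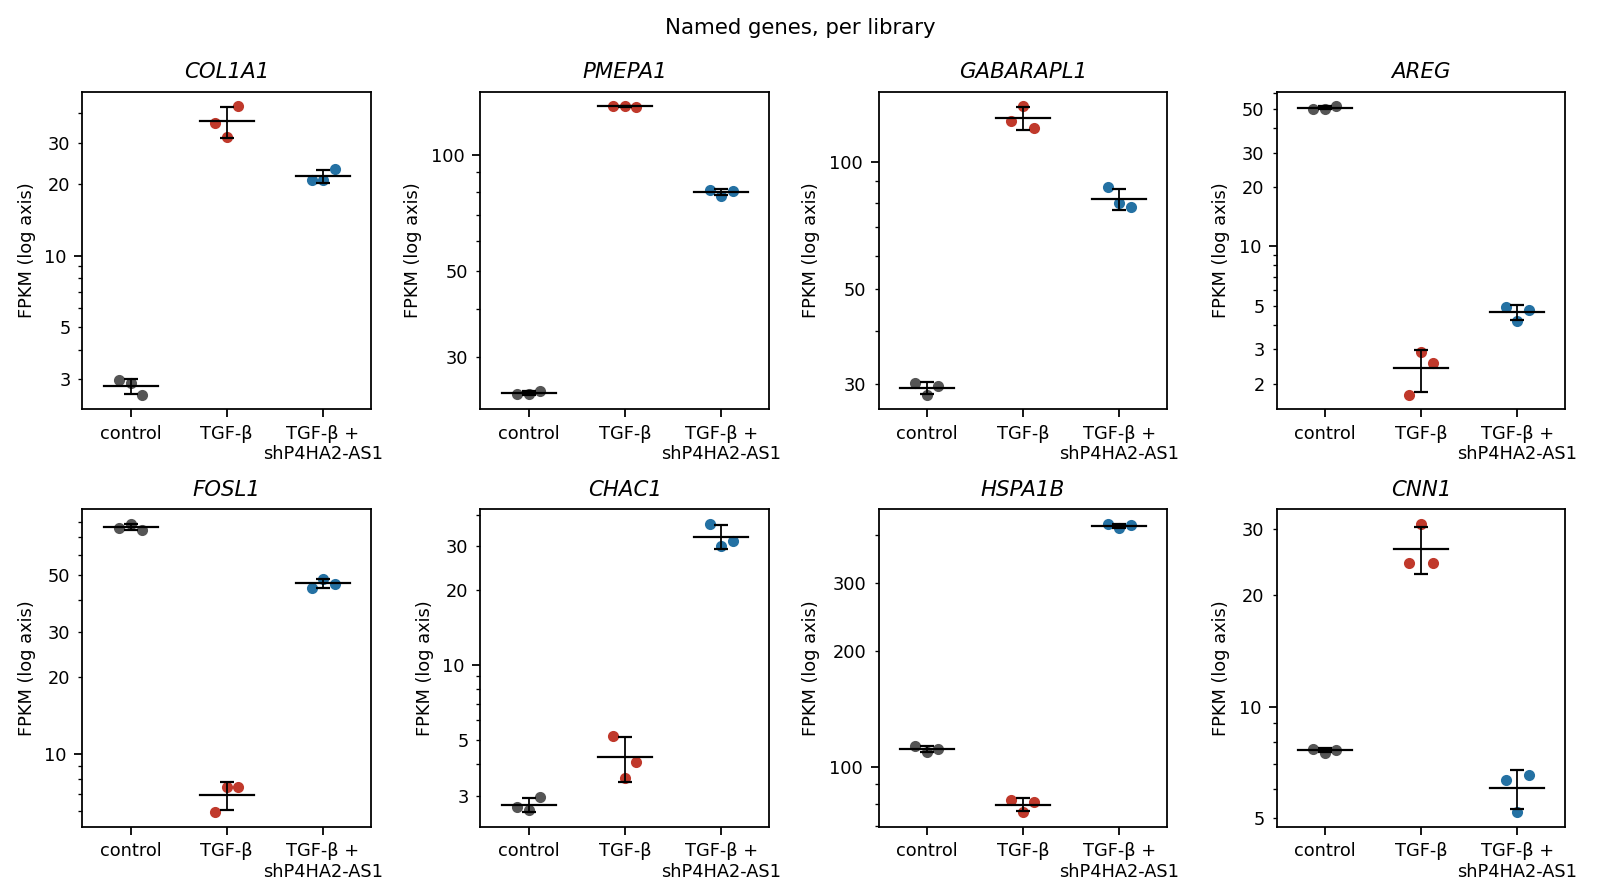
FPKM on a log axis of COL1A1, PMEPA1, GABARAPL1, AREG, FOSL1, CHAC1, HSPA1B and CNN1 in each of the 9 libraries, by group, with the mean and standard deviation of 3 libraries. CHAC1 was highest in the labelled knockdown libraries, at 32.7 FPKM against 4.28 with TGF-β alone and 2.76 in control cells.

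Stress response genes rose as a group. Of 25 tested genes in the unfolded protein and integrated stress response list, 17 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 4.27e-11; adjusted p = 0.175 with an estimated correlation). ASNS, which makes asparagine, rose 4.64-fold from 9.90 ± 1.46 to 49.8 ± 8.63 FPKM (SD, n = 3). Inflammatory and NF-κB targets rose, 9 up and 0 down of 21 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00037; adjusted p = 0.167 with an estimated correlation). The cytokine genes IL6 and CSF2 rose 3.85-fold and 2.75-fold.

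Lysosomal genes fell, 0 up and 15 down of 31 (1 and 16 adjusted over the list alone; camera adjusted p = 0.00145; adjusted p = 0.175 with an estimated correlation). TFEB, the regulator of lysosome genes, fell 2.22-fold and the cholesterol carrier NPC2 fell 1.71-fold. Cholesterol synthesis genes fell, 0 up and 13 down of 24 (0 and 14 adjusted over the list alone; camera adjusted p = 0.00121; adjusted p = 0.175 with an estimated correlation). SMAD targets fell, 5 up and 14 down of 27 (5 and 16 adjusted over the list alone; camera adjusted p = 0.0341; adjusted p = 0.175 with an estimated correlation). The cell cycle inhibitor CDKN2B fell 2.5-fold and ID2 rose 2.67-fold. Collagen-modifying enzymes fell, 3 up and 9 down of 18 (3 and 10 adjusted over the list alone; camera adjusted p = 0.0341; adjusted p = 0.234 with an estimated correlation). The cross-linking enzymes LOXL4 and LOXL1 fell 3.42-fold and 3.01-fold. The SMAD call was lost without TGF-β replicate 1 (adjusted p = 0.0588) or labelled knockdown replicate 2 (adjusted p = 0.0542). The collagen-modifying call was lost under quantile normalization (adjusted p = 0.0615), and without TGF-β replicate 1 (adjusted p = 0.0588), TGF-β replicate 3 (adjusted p = 0.0507) or labelled knockdown replicate 1 (adjusted p = 0.0592).

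The other lists did not pass. Extracellular matrix genes had 2 up and 9 down of 20 by either adjustment (camera adjusted p = 0.053), with LUM falling 2.83-fold and LAMB3 rising 2.37-fold, and the list did pass without TGF-β replicate 2 (adjusted p = 0.000798) or labelled knockdown replicate 3 (adjusted p = 0.0373). Contractile genes had 4 up and 8 down of 18 by either adjustment; CNN1 fell 3.92-fold and CALD1 2.79-fold. Epithelial junction genes had 2 up and 8 down of 18 by either adjustment, with the cadherin genes CDH16 and CDH6 falling 2.33-fold and 2.31-fold. Autophagy genes had 6 up and 8 down of 39 (6 and 9 adjusted over the list alone), and GABARAP fell 1.85-fold. Hypoxia and glycolysis genes had 5 up and 15 down of 28 (6 and 16 adjusted over the list alone), against a 4.33-fold rise of the vessel growth factor VEGFA. NRF2 genes had 9 up and 5 down of 21 (9 and 6 adjusted over the list alone), led by the heme oxygenase HMOX1, 4.88-fold up. Fatty acid oxidation genes had 1 up and 8 down of 24 by either adjustment, although CPT1A rose 1.80-fold. Tubular injury genes had 3 up and 8 down of 14 (4 and 8 adjusted over the list alone), with GDF15 rising 3.51-fold and SOX4 falling 2.41-fold. Proximal tubule genes had 1 up and 4 down of 9 (1 and 5 adjusted over the list alone), PDZK1 falling 2.51-fold and CYP27B1 rising 2.25-fold. Cell cycle genes had 7 up and 10 down of 37 by either adjustment, MCM6 falling 1.84-fold, and mesenchymal genes had 3 up and 2 down of 15 by either adjustment, ZEB1 rising 1.57-fold. Interferon-stimulated genes had 1 up and 4 down of 23 (0 and 2 adjusted over the list alone), with IRF9 falling 1.44-fold.

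Mesenchymal genes had a median of -0.02 but a mean of 0.01 and ran up in camera. Autophagy genes ran up in camera with a mean of -0.06 and a median of 0. The number of lists that passed was 6, and it was 13 without TGF-β replicate 2 and 11 without labelled knockdown replicate 3. Without TGF-β replicate 2 the lists added, besides extracellular matrix, were epithelial junction (adjusted p = 0.0471), proximal tubule (0.0294), tubular injury (0.0471), hypoxia and glycolysis (0.0191), fatty acid oxidation (0.044) and NRF2 (0.0434). Without labelled knockdown replicate 3 they were epithelial junction (0.0226), proximal tubule (0.0421), hypoxia and glycolysis (0.0497) and fatty acid oxidation (0.0421). With no filter they were extracellular matrix, epithelial junction and proximal tubule (0.03 each), tubular injury (0.0459) and NRF2 (0.0184). NRF2 genes also passed under quantile normalization (0.0372), at 5 FPKM (0.034) and with the length trend removed (0.0234), proximal tubule genes at 5 FPKM (0.0127), fatty acid oxidation under quantile normalization (0.0372) and extracellular matrix with the length trend removed (0.00989).

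**Figure D3:**
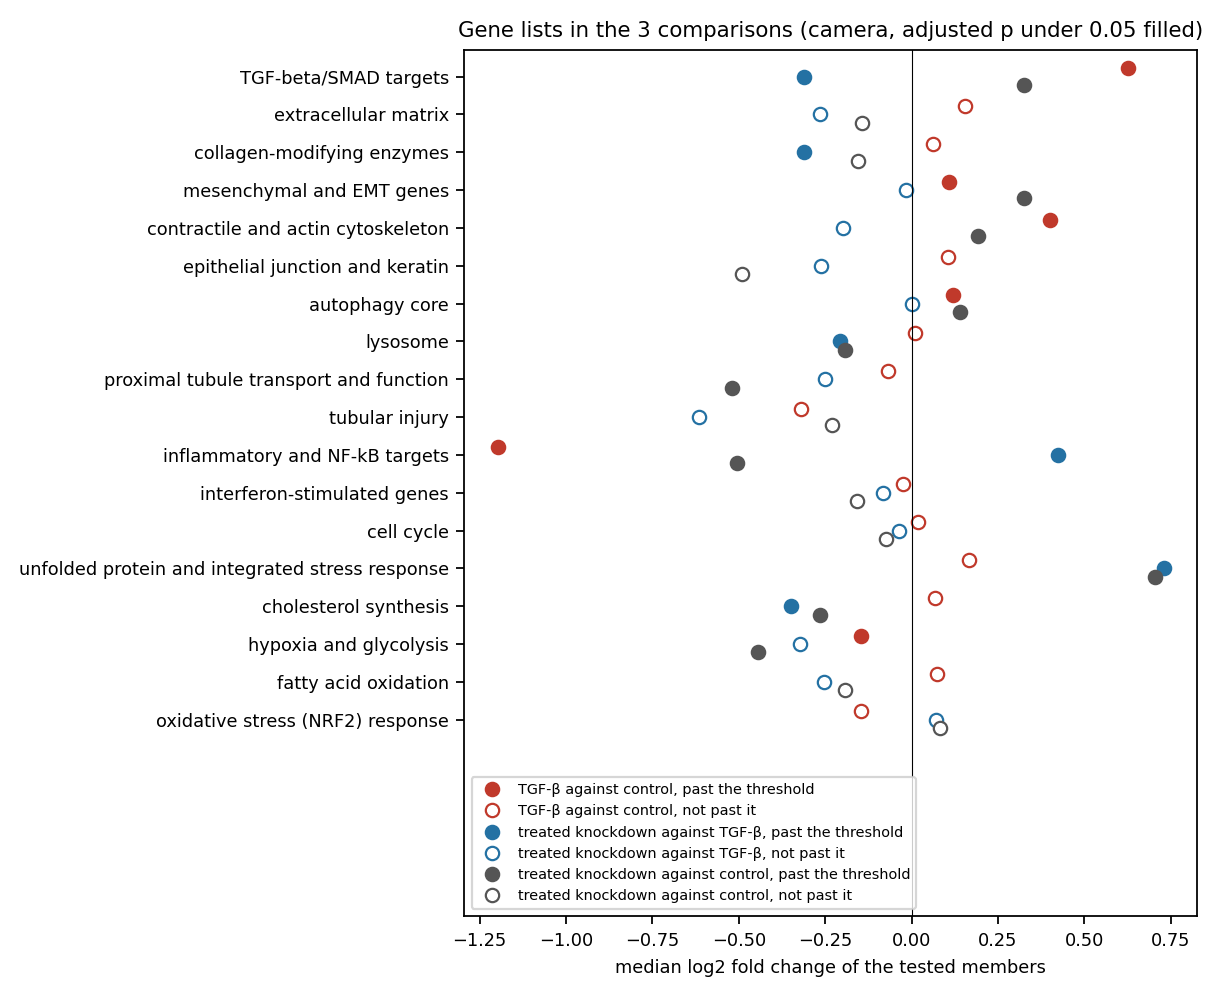
Median log2 change of each fixed gene list in the 3 comparisons, with filled points for lists that passed camera at an adjusted p under 0.05. The stress response list had medians of 0.73 and 0.70 in the labelled knockdown libraries against TGF-β and against control, and 0.17 with TGF-β alone.

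The third question was how many genes that answered TGF-β changed the opposite way in the labelled knockdown libraries, called moved back here. Such a gene may have stopped short of the control level or passed it. Of the 2864 genes changed by TGF-β, 1653 (57.7%) changed the opposite way in the labelled knockdown libraries, 896 that rose and then were lower and 757 that fell and then were higher. In the same direction 201 genes changed, 50 up and 151 down in both. With at least 2-fold changes in both comparisons, 137 genes changed in opposite directions and 5 in the same direction. Set against untreated control cells, 135 genes that rose with TGF-β were called lower in the labelled knockdown libraries. Another 108 that fell with TGF-β were called higher there than in control cells. FOSL1 fell from 76.7 ± 2.23 to 6.96 ± 0.87 FPKM with TGF-β and stood at 46.3 ± 1.89 FPKM in the labelled knockdown libraries (SD, n = 3). CSDC2 went from 0.48 ± 0.13 to 21.9 ± 1.61 and then 4.66 ± 0.49 FPKM, and the transcriptional repressor gene HES6 from 2.32 ± 0.20 to 23.4 ± 4.10 and then 4.98 ± 0.32 FPKM. KRTAP2-3, a keratin-associated gene with near-identical copies, went from 9.22 ± 0.44 to 1.04 ± 0.22 and then 7.28 ± 0.67 FPKM. NDST1, a heparan sulfate enzyme gene, also moved back but with a wide spread (log2 changes 2.19 ± 0.53 and -2.02 ± 0.53), and its calls did not hold in every alternative. The TGF-β call of NDST1 was lost without control replicate 1 (adjusted p = 0.0602), control replicate 3 (0.0609) or TGF-β replicate 1 (0.0579). Its other call was lost without TGF-β replicate 1 (adjusted p = 0.0554), labelled knockdown replicate 1 (0.0634) or labelled knockdown replicate 2 (0.0633), and with a pseudocount of 0.1 (log2 change -2.81, adjusted p = 0.0513).

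The TGF-β libraries enter both comparisons, which alone makes opposite signs more common. In 100 simulations with no true change, at most 1 gene was called in opposite directions. Without true changes almost no gene is called in either comparison, so this maximum does not show how many opposite calls sharing adds. Across genes, which are not independent replicates, the correlation of the fold changes was -0.55, against -0.50 in those simulations. Their covariance was -0.11, against -0.01 simulated, a difference of -0.10. With groups of equal size and independent noise, the simulated correlation is fixed at about -0.50 by construction. Independent lists of these sizes would share 280.4 genes that rose and then were lower and 236.6 that fell and then were higher, and 211.9 up and 313.2 down in both. The 3 TGF-β libraries cannot be divided into parts of at least 2, so part of the excess may come from sharing them.

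**Figure D4:**
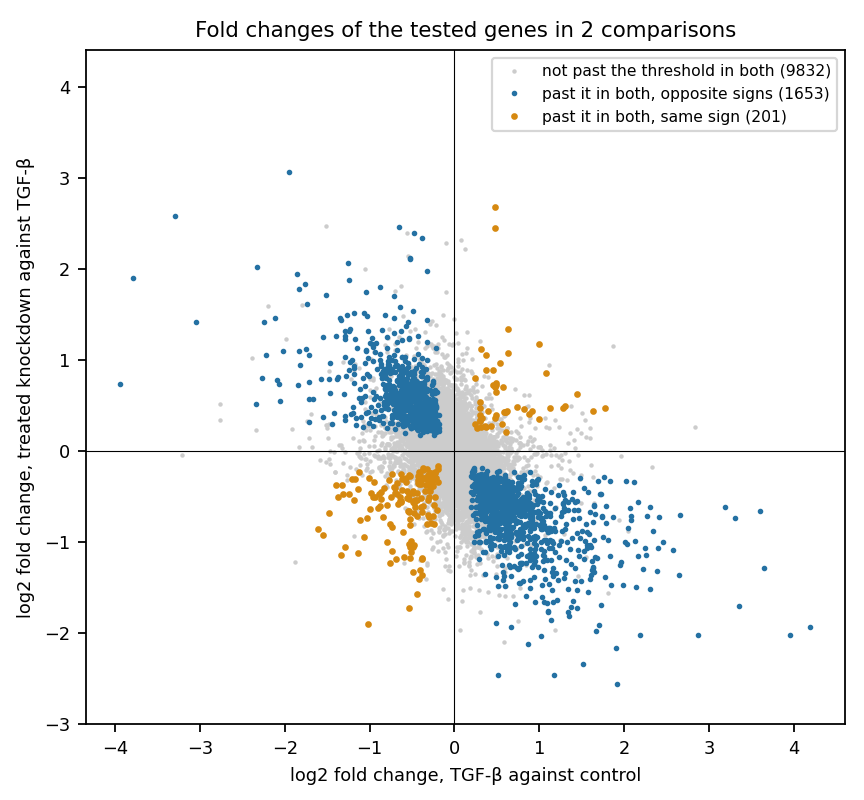
Log2 fold change of each tested gene with TGF-β against control and in the labelled knockdown libraries against TGF-β. Coloured points are genes called in both comparisons, 1653 in opposite directions and 201 in the same direction.

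The last comparison set the labelled knockdown libraries with TGF-β against untreated control cells. Of 11686 genes, 3089 changed, 1248 up and 1841 down, and 419 changed at least 2-fold (173 up, 246 down). The balance was 1572 up and 1590 down under median-of-ratios scaling, 1586 up and 1630 down under quantile normalization, 1321 up and 1827 down under upper-quartile scaling, and 1687 up and 1676 down with the transcript length trend removed. CHAC1 rose 8.94-fold and IL11 8.52-fold, IL11 from 4.56 ± 0.63 to 46.2 ± 2.28 FPKM (SD, n = 3), while CAVIN2 fell 9.53-fold and AREG 9.21-fold. The RNA-binding protein gene RBM27 rose 8.14-fold with a wide standard error (log2 change 3.03 ± 0.50, limma adjusted p = 0.00257). ULK1 stayed 3.75-fold above control (limma adjusted p = 6.34e-05), and TRIM32 had a log2 change of 0.20 ± 0.08 (adjusted p = 0.108). Of the 2864 genes changed by TGF-β, 1124 (39.2%) were also called in the same direction here, 482 up and 642 down. Independent lists would share 144.5 and 238. In the opposite direction, 135 that rose with TGF-β were called below control and 108 that fell were called above it. There independent lists would share 213.2 and 161.4. The control libraries enter both of these comparisons. Across genes the correlation of the fold changes was 0.461, against 0.501 simulated with no true change. The covariance of the fold changes was 0.09, against 0.01 simulated. Here too the simulated correlation is fixed by construction.

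Of the lists, 10 passed. Stress response genes rose, 21 up and 0 down of 25 (22 and 0 adjusted over the list alone; camera adjusted p = 2.68e-17; adjusted p = 0.0879 with an estimated correlation). SMAD targets had 12 up and 8 down of 27 (13 and 8 adjusted over the list alone; adjusted p = 0.00235; adjusted p = 0.0879 with an estimated correlation). Mesenchymal genes had 7 up and 2 down of 15 by either adjustment (adjusted p = 0.00404; adjusted p = 0.229 with an estimated correlation). Autophagy genes had 8 up and 1 down of 39 (11 and 2 adjusted over the list alone; adjusted p = 0.00235; adjusted p = 0.205 with an estimated correlation). Contractile genes had 7 up and 2 down of 18 (8 and 3 adjusted over the list alone; adjusted p = 0.0423; adjusted p = 0.149 with an estimated correlation), a call lost with a filter at 5 FPKM (adjusted p = 0.0603), and without control replicate 1 (0.0548), control replicate 3 (0.0642) or labelled knockdown replicate 3 (0.0651).

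Lower than in control cells were lysosomal genes, 1 up and 12 down of 31 (1 and 15 adjusted over the list alone; camera adjusted p = 0.00235; adjusted p = 0.151 with an estimated correlation). Hypoxia and glycolysis genes had 4 up and 19 down of 28 (4 and 20 adjusted over the list alone; adjusted p = 0.00114; adjusted p = 0.0879 with an estimated correlation). NF-κB targets had 2 up and 12 down of 21 by either adjustment (adjusted p = 0.00296; adjusted p = 0.0879 with an estimated correlation). Cholesterol synthesis genes had 1 up and 10 down of 24 by either adjustment (adjusted p = 0.0072; adjusted p = 0.206 with an estimated correlation). Proximal tubule genes had 1 up and 5 down of 9 (1 and 8 adjusted over the list alone; adjusted p = 0.00296; adjusted p = 0.0879 with an estimated correlation). The other lists did not pass: extracellular matrix (4 up and 6 down; 5 and 6 adjusted over the list alone), collagen-modifying enzymes (2 and 7 by either), epithelial junction (4 and 11; 5 and 11), tubular injury (5 and 6 by either), fatty acid oxidation (2 and 7; 2 and 8), cell cycle (2 and 10; 3 and 10), NRF2 (6 and 6; 7 and 6) and interferon-stimulated genes (1 and 1; 0 and 0). Fatty acid oxidation had an adjusted p of 0.0652 and passed under 8 alternatives: no filter (0.0446), median-of-ratios (0.0415), upper-quartile (0.0465) or quantile scaling (0.0311), curated transcripts (0.0453), the length trend removed (0.0395), and without control replicate 1 (0.0495) or labelled knockdown replicate 1 (0.0417).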

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

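Tests of TGF-β replicate 2 on the moved-back genes, of interferon genes, of a control hairpin and of the P4HA2-AS1 level were chosen after the results were seen. The others in this part were written down first. The test with divided TGF-β libraries was written down for 3 divisions and scored where 1 library served the TGF-β response.

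Transcripts that the gene table does not name also changed, a signal outside the data used for the comparisons. Of 6500 such transcripts tested in limma, 110 changed with TGF-β (63 up, 47 down), 88 in the labelled knockdown libraries against TGF-β (37 up, 51 down) and 81 against control (37 up, 44 down). Their genes were not identified here.

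The opposite movement of 1653 genes may come from shared libraries, from TGF-β replicate 2 or from transcript length. The TGF-β libraries were divided so that none served both comparisons. The correlation across genes was then -0.39, -0.37 and -0.36 (highest -0.356) when 1 library served the TGF-β response. It was -0.42, -0.30 and -0.41 when 1 served the knockdown effect. Noise independent between the shared libraries is therefore not the whole cause. An offset common to all TGF-β libraries stays in every division, with opposite signs in the comparisons, so these divisions cannot exclude it. Without TGF-β replicate 2 the count was 2193, and with the length trend removed 1795, which argues against both as the cause. An effect of the hairpin on the response to TGF-β stays a hypothesis, because vector and target cannot be separated.

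The rise of stress genes may be a response to hairpin RNA or to the vector. The interferon-stimulated list had a median of -0.083 in the labelled knockdown libraries against TGF-β, which argues against an interferon response to the hairpin. Without TGF-β replicate 2 the stress list had a median of 0.811, so that library is not the cause. Other heat shock factor 1 targets, besides HSPA1A and HSPA1B, had a median of 0.858, with 17 up and 1 down of 19 (camera p = 1.71e-11, p = 0.067 with an estimated correlation). Vector, transduction or selection effects and loss of P4HA2-AS1 cannot be told apart, since the labels describe no library with a control hairpin.

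The lack of a fall of P4HA2-AS1 in the labelled knockdown libraries is consistent with a level too low to measure, as its highest value in any library was 0.0756 FPKM. No biological explanation was tested.

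With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 2864 genes for TGF-β against control and the highest other split 1, with 4171 and 795 at an unadjusted p under 0.05. For labelled knockdown against TGF-β the real split called 4252 and the highest other 2, with 5464 and 1281 at an unadjusted p under 0.05. Against control the real split called 3089 and the highest other 0 in limma, with 4415 and 226 at an unadjusted p under 0.05. In each comparison the real split was the 1 split with as many. Every other split mixes the 2 groups, so a real difference between them widens its residual spread and lowers its calls. The counts of the other splits are therefore not rates of false calls.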

How the results depend on the processing

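Scalings, the filter at 5 FPKM, array weights, curated transcripts and the length correction were chosen after seeing the data; the other alternatives were planned. Requiring a 2-fold change left 448, 423 and 419 changed genes in the 3 comparisons and 137 moved back, by construction fewer. Array weights gave 5315 changed genes for TGF-β against control, 4706 for labelled knockdown against control, 12 lists for labelled knockdown against TGF-β and 3108 moved back, but that fit of the weights stopped before convergence. Weights fitted gene by gene gave 4383 genes, 13 lists and 2519 moved back; TGF-β replicate 2 had a weight of 0.142. With no filter 11 lists passed for labelled knockdown against TGF-β; the cause was not tested. An estimated correlation left 1, 0 and 0 lists in camera (4, 3 and 6 at an unadjusted p under 0.05), keeping 1 of 22 list calls, and fry gave 11, 15 and 16. By construction the estimated correlation leaves fewer degrees of freedom and fry does not compare a list with other genes. Outside the estimated correlation 18 of 22 list calls were kept under every setting. The other calls were also lost under scaling (mesenchymal, TGF-β against control: median-of-ratios 0.0606, upper quartile 0.0576, quantile 0.0899; collagen-modifying, labelled knockdown against TGF-β: quantile 0.0615), with a replicate block (SMAD, labelled knockdown against TGF-β: 0.0601) and at 5 FPKM (contractile, labelled knockdown against control: 0.0603).

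Leaving out 1 library at a time gave 1974 to 3735, 3285 to 4801 and 2080 to 4427 changed genes, 5 to 7, 4 to 13 and 9 to 11 lists, and 1191 to 2193 genes moved back, the highest gene counts without TGF-β replicate 2. Fold changes were reversed for ITGB8 with TGF-β (0.16, curated transcripts only, adjusted p = 0.845; negative with any 1 library left out), ULK1 in labelled knockdown against TGF-β (0.50, curated only; -0.22 to 0.093 with 1 library left out) and P4HA2 in the same comparison (-0.58 to 0.095 with 1 library left out); neither ULK1 nor P4HA2 was called there as reported, and the cause was not tested.

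TRIM32 passed in labelled knockdown against control with array weights (adjusted p = 0.0286 and, gene by gene, 0.0337). Of 107 named calls 93 were kept under every setting. The 14 lost under at least 1 included EHHADH, FDPS, STAT2, MCM10, NDST1 in both comparisons, S100A4, MVK, IFIT3, HK2, ITGB8 and LOXL4, the last 3 of these with curated transcripts only. Replicate numbers were not taken to pair libraries, since 2 of 9 same-number pairs had a residual correlation over 0.1 (-0.01 to 0.22). Both of these pairs joined a TGF-β and a labelled knockdown library (0.18 for replicate 2, 0.219 for replicate 3). Pairs of unlike number ran from -0.239 to 0.088, so pairing between those 2 groups is not excluded. Of the 9 libraries 5 correlated best with a library of their own number, and 1 did so in both other groups. A replicate block gave 2856, 4319 and 3127 genes, sharing 2632, 4020 and 2872. Planned count models, count normalizations and count filters were not run because the table holds no counts, and depth limits could not be computed.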

Other observations

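Tests of uniform weakening, heat shock targets and MAPK output were written down before their values were seen. Chosen after the results were seen were the lists of amino acid handling and metallothionein genes and the parts of the stress list. The list medians in divisions with no shared library were also chosen then.

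Within the stress list, 12 of the 12 genes of the ATF4 arm were called up in the labelled knockdown libraries against TGF-β, with a median of 1.53, and endoplasmic reticulum genes had 5 up and 1 down of 13, with a median of 0.37 (1.35 to 1.63 and 0.198 to 0.481 over 12 settings). These parts were formed after the list's rise had been seen, so no p is given for them and their difference was not tested. Amino acid transporters had 6 up and 1 down of 9 (median 1.01, 0.955 to 1.08 over these settings; camera p = 1.62e-05; p = 0.0243 with an estimated correlation). Cytosolic tRNA synthetases had 10 up and 1 down of 20 (median 0.35, 0.301 to 0.4; camera p = 0.00013; p = 0.101 with an estimated correlation). Metallothioneins, which bind zinc and copper, had 0 up and 2 down of 5 (median -0.38, -0.401 to -0.109; camera p = 0.246; p = 0.57 with an estimated correlation). These p-values are unadjusted over 7 lists and 3 comparisons.

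Heat shock genes other than HSPA1A and HSPA1B moved the other way with TGF-β alone, with 1 up and 12 down of 19 and a median of -0.38 (camera p = 4.8e-06; p = 0.18 with an estimated correlation). In 6 divisions with no TGF-β library shared their medians were -0.50 to -0.26 with TGF-β and 0.57 to 0.92 in the labelled knockdown libraries against TGF-β. Such divisions do not remove an offset common to all TGF-β libraries. Against control the labelled knockdown libraries had 12 up and 1 down, with a median of 0.34 (camera p = 5.64e-08; p = 0.122 with an estimated correlation).

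One hypothesis is that the labelled knockdown libraries weakened the whole TGF-β response by 1 factor. Across the 448 genes changed at least 2-fold by TGF-β, the retained share was 0.56, and 61.2% lay more than 3 standard errors from it. This argues against a uniform factor as the only change. Hairpin or vector effects apart from the TGF-β response would also scatter the shares, so a uniform weakening beside them stays possible. The median retained share was 0.46 for genes that rose and 0.69 for genes that fell. Over the 12 SMAD targets that TGF-β changed at least 2-fold the retained share ran from 0.43 (TGFB1) to 1.88 (ID1), and 3 were above 1, with BHLHE40 at 1.37 and SNAI1 at 1.08, examples chosen after their values were seen.

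The EGF receptor ligands and FOSL1 were low with TGF-β, and FOSL1 and EREG were higher again in the labelled knockdown libraries, so lower and then higher MAPK pathway output may be a candidate explanation. A list of 10 other output genes, 9 of them tested and adapted here rather than taken from a published score, had a median of -0.55 with TGF-β (1 up, 7 down; camera p = 0.000355; p = 0.0119 with an estimated correlation). In the labelled knockdown libraries against TGF-β its median was 0.961 (7 up, 0 down; camera p = 1.17e-07; p = 0.00185 with an estimated correlation). Against control its median was 0.41 (0.365 to 0.826 over 12 settings; 5 up, 0 down; camera p = 0.000518; p = 0.0134 with an estimated correlation). The genes that prompted the explanation differed from the list there, as they stayed below control in the labelled knockdown libraries. AREG measured 4.61 FPKM against 50.6 in control cells, EREG 14.0 against 54.5 and FOSL1 46.3 against 76.7. Shared TGF-β libraries alone favour opposite signs (a correlation of -0.50 across genes with no change). In 6 divisions with no library shared the medians were still -0.68 to -0.56 with TGF-β. They were 0.89 to 1.11 in the labelled knockdown libraries against TGF-β. The divisions remove noise independent between libraries but not an offset common to all TGF-β libraries, which stays open. Kinase activity was not measured, and the role of the vector stays open.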
